A study of Arabidopsis halleri with 24 samples.

How the data were processed

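Biotin-labelled total RNA, recorded as from Arabidopsis halleri, was hybridised to 24 ATH1 arrays, whose probes were designed on A. thaliana. Titles placed the arrays in 8 groups of 3, which combined an accumulating or non-accumulating bulk, an organ (whole root system or rosette leaves) and control or high-zinc medium. The treatment labels gave 25 µM zinc for the high-zinc groups, and the growth labels gave 10 h of light in a growth room with full mineral medium. Replicate 1 of the non-accumulating control roots carried the source name halleri, whereas the other 23 arrays carried the name of a bulk. That array was kept in the group its title gave, and whether it came from a bulk is not known apart from the title.

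The deposited values were linear MAS5 signals in intensity units for 22810 probe sets. The mean of each array, after the lowest and highest 2% of probe sets were trimmed, was 100.0 in all 24 columns, so the values were used as the authors scaled them. The MAS5 version, the scaling target and detection calls are not given in the sources used here. Signals ranged from 0.012 to 12842. Array signals have no counting depth, and the number of arrays limits the precision.

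The 64 control probe sets were left out, which left 22746. The probe table named 1 gene for 13513 probe sets, several genes for 503 and none for 8794. Genes were named only from probe sets with 1 symbol, and other probe sets are given by their identifier. Sequence differences between A. halleri and the A. thaliana probes can lower a signal, so levels were compared within a probe set and not between genes. This does not remove an effect of sequence differences between the bulks, which was not tested.

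Tests used limma 3.58.1 in R 4.3.3 on log2(signal + 16), with a mean per group, empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment at 0.05. Roots and leaves were fitted separately with 12 arrays each, and all 24 arrays were fitted together for root against leaf and for the organ by bulk interaction. A probe set was kept when its highest group mean lay above the median of all values in the fit, which was a signal of 56.3 in roots, 53.3 in leaves and 54.8 over all arrays. This left 12489, 12685 and 14399 probe sets. In each organ the bulk difference and the zinc response were averaged over the other factor, followed by their interaction and the comparisons of 3 arrays against 3. Log2 changes are accumulating minus non-accumulating, high zinc minus control, or root minus leaf, and SE is the moderated standard error.

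Before the data were examined, 24 gene lists with 357 distinct genes were fixed. The probe table named 49 of these genes, and 9 lists had at least 3 named members. A further 17 lists were set from the gene symbols after the probe table was seen and before any test; they are called added lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of the same kind within a comparison, and again with an estimated correlation. A few lists that had passed camera for zinc were then picked, and their means were compared by exact permutation tests, two-sided, within each bulk.

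Genes were named by a rule written beforehand. It took the 10 largest rises and 10 largest falls past the threshold with no overlap between the replicates compared, or 5 of each in the smaller comparisons, up to 4 members per list past the threshold, and 14 metal genes regardless of value. Of these 14, ZIP6 and ZIP9 were named in the probe table, and the other metal genes were not analysed here. Any gene named outside this rule was chosen after its values were seen.

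On simulated data for the zinc response in leaves, 68% of changes of 2-fold and 98% of changes of 4-fold were recovered among 12685 probe sets. For the bulk difference in roots the shares were 84% and 96% among 12489 probe sets, and for the bulk by zinc interaction in leaves 6% and 50%. Changes of 1.5-fold were recovered in 22%, 42% and 0% of cases in these comparisons, in the same order. The simulated spread was independent between probe sets and arrays, so it held no structure shared by arrays of the same replicate number. The alternatives were other pseudocounts, other filters on low signals, quantile normalization, median centring, plain probe sets only, no variance trend, array weights, a replicate block, 1 fit of all arrays, and each array left out in turn. The leaf fits without replicate number 3 and with the clock gene GI as a covariate were added after the data were seen.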

Results

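The series measured transcript signals in roots and rosette leaves of bulks of plants, recorded as Arabidopsis halleri, that did or did not accumulate zinc. Each of the 8 groups had 3 arrays. The bulks are known to have been pooled from the progeny of a cross between A. halleri and the non-accumulating A. petraea. The array titles do not give this parentage. The comparisons ask which transcripts go with accumulation and with zinc supply. The labels do not say whether replicates came from separate plants or cultures, so p-values measure only the spread between arrays. Within a group, the correlation between arrays ranged from 0.936 to 0.962 in roots and from 0.869 to 0.963 in leaves. Arrays of the same organ from other groups gave 0.926 to 0.963 in roots and 0.866 to 0.964 in leaves, and root with leaf gave 0.663 to 0.799. The log2 ratio of 3' to 5' GAPDH signal, a sign of RNA integrity, lay between 1.19 and 1.73 over the arrays, and that of actin between 1.03 and 1.84.

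Photosynthesis genes were far lower in roots than in leaves. The light-harvesting antenna genes LHCB4.2 and LHCB4.1 were lower in roots by log2 changes of -6.76 (SE 0.21) and -6.57 (SE 0.18) over 12 arrays per organ. The photosystem genes PSAN, PSBY and PSBW changed by -6.44, -6.40 and -5.69, the chloroplast ATP synthase gene ATPC1 by -6.16 and the Rubisco activase gene RCA by -6.01. AT1G72290, which encodes a Kunitz-type inhibitor, fell from a mean signal of 4321 (SD 1097, n = 3) in non-accumulating control leaves to 30.1 (SD 45.1, n = 3) in the roots of the same bulk and medium, and its log2 change over all groups was -7.39. That root signal lay under the filter of 54.8, so the size of the change depends on the pseudocount: for AT1G72290, root against leaf, it was -9.31 with a pseudocount of 1 and -5.73 with 64. The same holds for the other genes of this paragraph except PSBW, AT1G49310 and AT5G10580, whose signals, averaged over the groups of an organ, lay above the filter in both organs. The defensin gene PDF1.2b changed by -6.21 on a probe set that can cross-hybridise, and AT1G09310 by -5.67. In the other direction, AT4G33720 was higher in roots by 7.46 (SE 0.14), AT3G13610, a feruloyl-CoA hydroxylase gene of coumarin synthesis, by 6.79 (SE 0.18), and the beta-glucosidase gene PYK10 by 4.74 (SE 0.15). AT3G62040, AT1G49310, AT1G26250, AT4G33710, AT5G10580, AT3G01190 and AT5G19890 rose by 4.98, 4.86, 4.86, 4.84, 4.75, 4.69 and 4.59.

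All 4 named photosynthesis markers were lower in roots, among them SBPASE (-4.16) and PRK (-4.30), with an adjusted p of 0.000142 for the list and an adjusted p of 0.0851 with an estimated correlation. All 3 named root markers were higher, with EXPA18 at 1.48 and EXPA7 at 0.80; the list gave an adjusted p of 0.0483, and 0.0851 as the p with an estimated correlation. Among the added lists, all 54 plastid-encoded genes and all 23 genes of the wider photosynthesis list were lower, with adjusted p of 0.0396 and 0.0468 under an estimated correlation. In the iron deficiency list 3 of 5 members were higher, AT3G13610, AT3G12900 (2.73) and AT1G28680 (2.42), PYE was lower (-0.33), and BHLH101 did not pass. The iron list as a whole gave an adjusted p of 0.0753, the cold and dehydration list 0.0604, the flavonoid list 0.191, the metal export list 0.275 and the sulfate assimilation list 0.539.

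Among metal genes, the ZIP family member ZIP9 was higher in roots by 0.76 (SE 0.14), ZIP6 differed by -0.07 (SE 0.12) without passing, the metal carrier gene MTP11 was lower by a log2 change of -0.92 and AT2G04620 by -0.31. The metallothionein gene MT1C was higher by 1.83 and the superoxide dismutase copper chaperone gene CCS by 0.51. In the cold and dehydration list COR15B (-3.28), COR15A (-2.91) and LTI30 (-0.80) were lower and COR47 (0.37) higher. APS4 (1.54) and APS3 (0.51), which encode ATP sulfurylases, were higher and the sulfite reductase gene SIR lower (-0.39). PDF1.4 (-1.08), GRX480 (-0.99), STZ (-1.98), BCAT4 (-0.55), DFR (-0.73), UGT78D2 (-0.30) and WRKY6 (-0.36) were lower, and SAG29 (0.83), AUR1 (0.77) and GI (1.08) higher.

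In all, limma placed 9776 of 14399 probe sets (67.9%) past the threshold, 5826 higher and 3950 lower in roots. Of these, 1922 and 1699 changed by more than 2-fold. The calls of CCS (adjusted p = 0.0553) and COR47 (0.0518) were lost with median centring, that of SIR (0.167) with quantile normalization, and that of WRKY6 without a filter (0.0579). Calls near the threshold also depended on single arrays. For WRKY6, root against leaf, the call was lost without any of 12 arrays, with the adjusted p up to 0.0910 without replicate 1 of the non-accumulating control roots. For SIR, root against leaf, it was at most 0.0674 without replicate 1 of the non-accumulating control leaves. For UGT78D2, root against leaf, it was at most 0.0549 without replicate 3 of the accumulating control roots. For CCS, root against leaf, it was at most 0.0558 without replicate 1 of the accumulating high-zinc roots. The root marker list gave up to 0.0609 without replicate 3 of the accumulating control leaves.

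In roots, high zinc went with higher signals of 4 of the 5 named iron deficiency genes, out of 20 genes in the list. AT3G12900, a scopoletin hydroxylase gene of coumarin synthesis, had a mean signal of 171 (SD 48.7, n = 3) in non-accumulating control roots and 1857 (SD 1199, n = 3) with high zinc, and 501 (SD 619, n = 3) and 1000.2 (SD 284, n = 3) in the accumulating bulk. Its log2 change over both bulks was 2.39 (SE 0.48). The iron-regulated transcription factor gene BHLH101 differed by 1.17 (SE 0.27), the coumarin genes AT3G13610 and AT1G28680 by 1.13 (SE 0.32) and 1.06 (SE 0.34), and PYE, a regulator of the iron response, by 0.10 (SE 0.16). The list of 5 was higher with an adjusted p of 4.12e-07 and a median of 1.13, and its adjusted p was 0.0618 with an estimated correlation. None of the 5 passed over all genes tested, and 4 were higher when adjusted over the list alone. The mean of the 5 genes differed by 1.17 (exact permutation p = 0.02), by 1.65 in the non-accumulating bulk (exact p = 0.1) and by 0.69 in the accumulating bulk (exact p = 0.4). The accumulating change was 1.17 without replicate 2 and 0.41 without replicate 1 of its control. With 3 arrays against 3 the smallest exact p is 0.1.

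**Figure D1:**
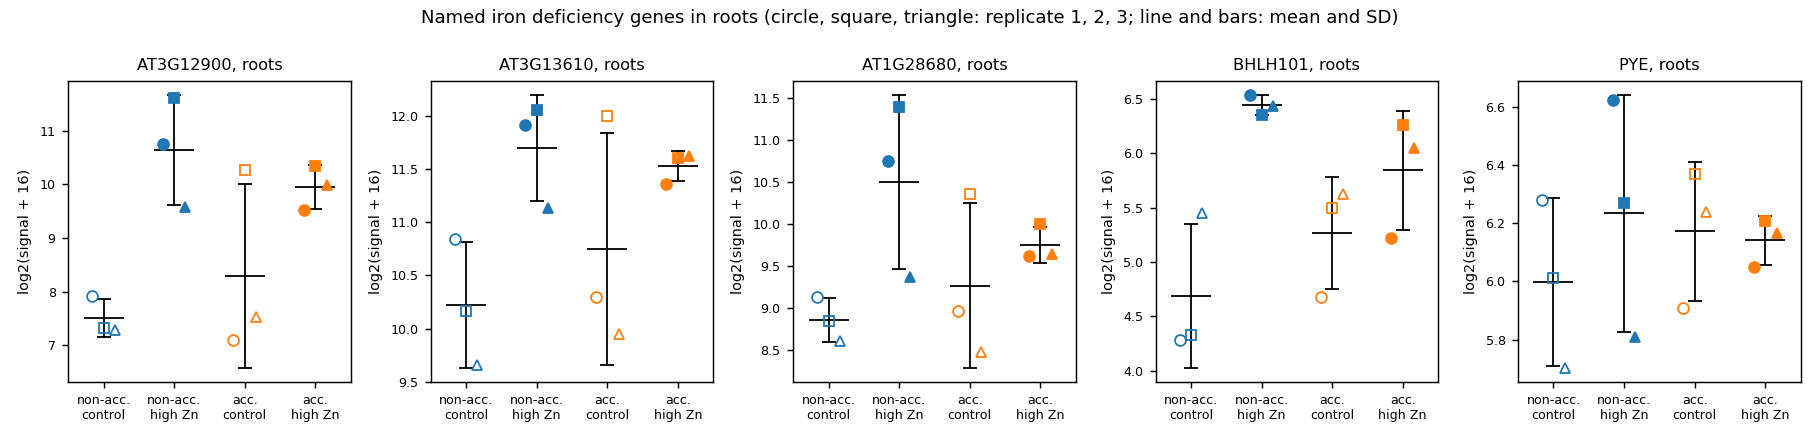
Log2(signal + 16) of the 5 named iron deficiency genes in the 12 root arrays, with blue symbols for the non-accumulating and orange for the accumulating bulk, open for control and filled for high zinc. Symbols give each array and black lines with bars the group mean and SD; replicate 2 of the accumulating control roots lay at 10.27 for AT3G12900, where the other arrays of its group lay at 7.09 and 7.53.

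The root marker list was also higher with zinc, with an adjusted p of 0.0271 and an adjusted p of 0.0824 with an estimated correlation. Its members differed unequally, with EXPA18 at 0.62 (SE 0.19), EXPA7 at 0.54 (SE 0.27) and PYK10 at 0.09 (SE 0.22), and only EXPA18 passed when adjusted over the list alone. EXPA18 and EXPA7 are expansin genes of root hairs. The adjusted p of the list was 0.162 without replicate 3 of the non-accumulating high-zinc roots and 0.0990 without replicate 1 of the non-accumulating control roots. It was 0.0642 without replicate 2 of the non-accumulating high-zinc roots, 0.0593 without replicate 1 of the accumulating control roots and 0.0557 without replicate 3 of the accumulating high-zinc roots (list root markers, zinc response in roots). Of the metal export list, AT3G58060, known as the manganese carrier gene MTP8, was higher by 0.90 (SE 0.23) and MTP11 lower by a log2 change of -0.28 (SE 0.11), both past the threshold only when adjusted over the list alone (0.00547 and 0.0425). The list itself gave an adjusted p of 0.721, as did the flavonoid list, and the sulfate assimilation list gave 0.780. The Aurora kinase gene AUR1 differed by -0.56 (SE 0.12), SAG29 by 0.42 (SE 0.19), ZIP6 by -0.06 (SE 0.12) and ZIP9 by -0.00202 (SE 0.21), without passing over all genes. AUR1 and SAG29 were the only members of their lists tested, so their p of 0.000401 and 0.0428 are unadjusted. Of the added lists, the plastid-encoded genes were lower with a median of -0.20 over 50 members and an adjusted p of 8.97e-06; that p was 0.756 with an estimated correlation and 0.132 without replicate 3 of the non-accumulating control roots.

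Over all 12489 probe sets limma called 0 for zinc in roots, with 854 at an unadjusted p under 0.05 and 624 expected by chance. It also called 0 in the non-accumulating bulk (1018 unadjusted) and 0 in the accumulating bulk (361). Leaving out replicate 1 of the non-accumulating control roots, the array with source name halleri, kept these counts at 0 among 12543 probe sets. The unadjusted counts were then 755 for both bulks, 738 in the non-accumulating and 324 in the accumulating bulk. Without replicate 2 of the accumulating control roots, 6 probe sets were called for zinc, all higher, among them AT3G12900 at 2.89 (adjusted p = 0.00247), and 10 in the non-accumulating bulk. Without replicate 3 of the non-accumulating high-zinc roots, 1 was called in each of these comparisons. Across 12489 genes, which are not independent replicates, the zinc changes of the separate bulks correlated at r = 0.196.

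In leaves, AT3G09580 fell with high zinc in both bulks. Its mean signal was 270 (SD 37.0, n = 3) in non-accumulating control leaves and 82.6 (SD 47.1, n = 3) with high zinc, and 221 (SD 17.1, n = 3) and 67.2 (SD 33.6, n = 3) in the accumulating bulk. In the separate bulks the log2 change was -1.63 and -1.58, without passing (adjusted p = 0.564 and 0.478). Over both bulks it was -1.61 (SE 0.23, adjusted p = 0.0494), and every high-zinc leaf array lay below every control leaf array of its bulk. The naming rule required this separation, so it is not separate support. Another 3 probe sets without a listed gene changed by -1.90, -1.55 and 1.57 on the log2 scale, so the total was 4 of 12685, 1 higher and 3 lower. The call of AT3G09580 was lost without a variance trend (adjusted p = 0.0603), with median centring (0.0569), without a filter (0.102) and with a pseudocount of 1 (0.076). For AT3G09580, zinc response in leaves, the call was also lost without any 1 array except replicate 3 of the high-zinc groups, with the adjusted p from 0.0860 without replicate 3 of the accumulating control leaves to 0.222 without replicate 2 of that group.

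The mean log2 signal of 23 photosynthesis genes was lower in replicates 1 and 2 of the high-zinc leaves than in any control leaf array. In replicate 3 of high zinc this mean lay near or above the controls. The wider photosynthesis list, an added list, was lower with a median of -0.50 over 23 genes and an adjusted p of 9.15e-10; with an estimated correlation its adjusted p was 0.447. The mean of the list differed by -0.50 (exact permutation p = 0.08). The list means of the arrays were 10.04, 10.18 and 10.09 in non-accumulating control and 9.50, 9.23 and 10.29 in non-accumulating high-zinc leaves. In the accumulating bulk they were 10.03, 9.88 and 10.03 in control and 9.15, 9.07 and 10.04 in high zinc. The 4 fixed photosynthesis markers gave an adjusted p of 0.181, with RCA at -0.51 (SE 0.30) and LHCB4.1 at -0.47 (SE 0.24). The sulfate assimilation list gave 0.181, the flavonoid list 0.264, the metal export list 0.373, the iron deficiency list 0.659 and the cold and dehydration list 0.799. None of the 36 fixed-list members tested passed over all genes, ZIP6 (0.07, SE 0.21) and ZIP9 (-0.01, SE 0.15) included. UGT74B1 (0.46) gave 0.0301 when adjusted over its list alone. EXPA7 (-0.41), the only root marker tested in leaves, had an unadjusted p of 0.0375.

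**Figure D2:**
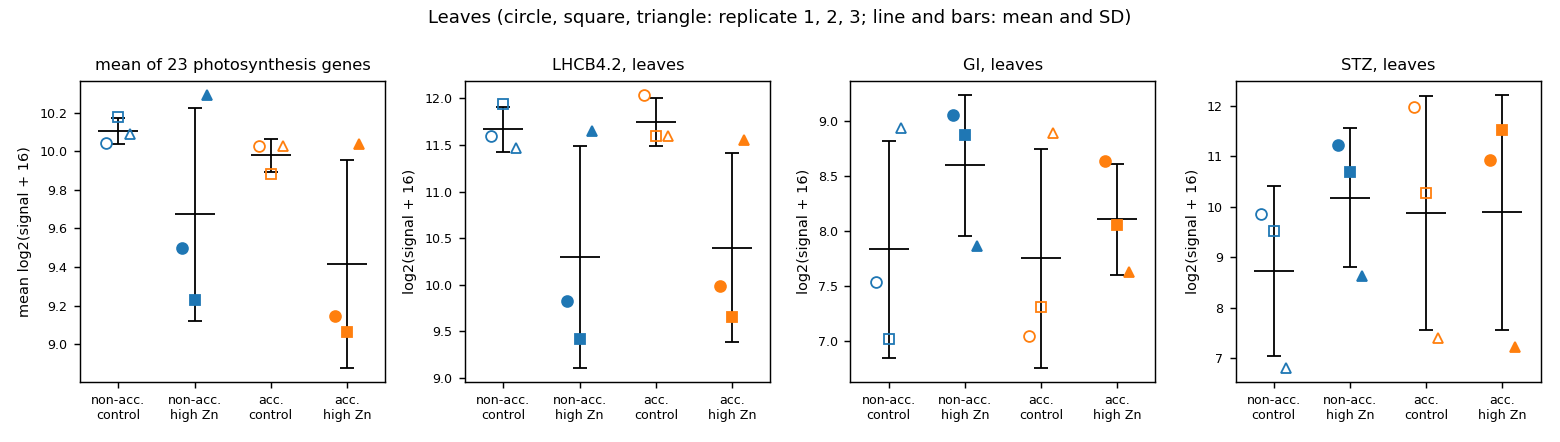
Log2(signal + 16) in the 12 leaf arrays for the mean of 23 photosynthesis genes, LHCB4.2, the clock gene GI and the zinc finger gene STZ, with colours, symbols, lines and bars as group, replicate, mean and SD. In the high-zinc groups replicate 3 stood at 10.29 and 10.04 for the photosynthesis mean, above replicates 1 and 2 at 9.07 to 9.50.

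Replicate 3 of the leaf groups stood apart from replicates 1 and 2 in general. With a term for replicate 3, 2889 probe sets differed, 1493 higher and 1396 lower, against 195 for replicate 3 of the roots and 0 for the other replicate numbers. STZ, a stress-induced zinc finger gene, was lower in leaf replicate 3 by a log2 change of -3.24, and SKU5 was higher by 2.29. The clock gene GI lay at 8.93 and 8.89 in control replicate 3 and at 7.86 and 7.63 in high-zinc replicate 3, against 7.02 to 7.54 and 8.06 to 9.05 in replicates 1 and 2. In an alternative added after this was seen, the leaf arrays of replicate 3 were left out, and 1219 of 13188 probe sets then differed between high zinc and control, 574 higher and 645 lower. GI differed as well, by 1.42 (SE 0.19), so in these arrays the zinc groups are also groups of high and low GI. The cold-induced gene COR27 was higher by 3.07 (SE 0.21), AT3G56410 by 2.36 (SE 0.22), the linker histone gene HIS1-3 by 2.36 (SE 0.28), AT1G47400 by 2.27 (SE 0.32) and TIL by 2.03 (SE 0.18). LHCB4.2 (-2.07, SE 0.17), AT3G09580 (-1.97, SE 0.15), MSRB6 (-1.93, SE 0.26) and LHCB4.3 (-1.70, SE 0.21) were lower. In that fit 13 of the 23 photosynthesis genes were lower and 0 higher, and the list's adjusted p was 1.82e-13, or 0.278 as the p with an estimated correlation.

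For the zinc response of the non-accumulating bulk in leaves limma called 1 probe set without a listed gene, lower by a log2 change of -2.36 (590 at an unadjusted p under 0.05). For the zinc response of the accumulating bulk in leaves it called 0 (731). Without the leaf arrays of replicate 3 these counts were 408 and 217, and with array weights 759 and 1193. A replicate block also raised the counts for the accumulating bulk and for both bulks, as given below with the other settings. The call in non-accumulating leaves remained in single omissions only without replicate 1 of its control or replicate 3 of the accumulating high-zinc leaves. The count of 4 for both bulks was 12 without replicate 3 of the non-accumulating high-zinc leaves and 7 without replicate 3 of the accumulating control leaves. It was 1 or 2 without any of the other arrays except replicates 1 and 3 of the accumulating high-zinc leaves. Across 12685 genes the zinc changes of the separate bulks correlated at r = 0.465.

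Between the bulks, ZIP6, a member of the zinc and iron transporter family, had higher signals in accumulating plants in both organs. In roots its mean signal was 178 (SD 38.7, n = 3) in the non-accumulating and 218 (SD 18.5, n = 3) in the accumulating control group, and 148 (SD 19.6, n = 3) and 238 (SD 13.5, n = 3) with high zinc, a log2 difference of 0.46 (SE 0.12). In leaves the difference was 0.83 (SE 0.21). Both passed when adjusted over the list alone (0.00341 and 0.00435), which held only 2 named genes of 14. Neither passed over all genes (0.457 and 0.820). Whether the bulks differ in sequence under the ZIP6 probe set was not tested. ZIP9 differed by 0.45 (SE 0.21) in roots and by -0.34 (SE 0.15) in leaves, the latter at 0.044 when adjusted over the list alone. The organ by bulk interaction of ZIP9 was 0.79 (SE 0.27, adjusted p = 0.999), and that of ZIP6 -0.37 (SE 0.24, adjusted p = 0.999), with ZIP9 at 0.0181 when adjusted over the list alone. In leaves the defensin gene PDF1.4 differed by 1.01 (SE 0.23) and the transcription factor gene WRKY6 by 0.68 (SE 0.21), with adjusted p of 0.735 and 0.875 over all genes. PDF1.4 gave 0.00188 when adjusted over its list alone, and WRKY6, the only member of its list tested there, had an unadjusted p of 0.00708.

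**Figure D3:**
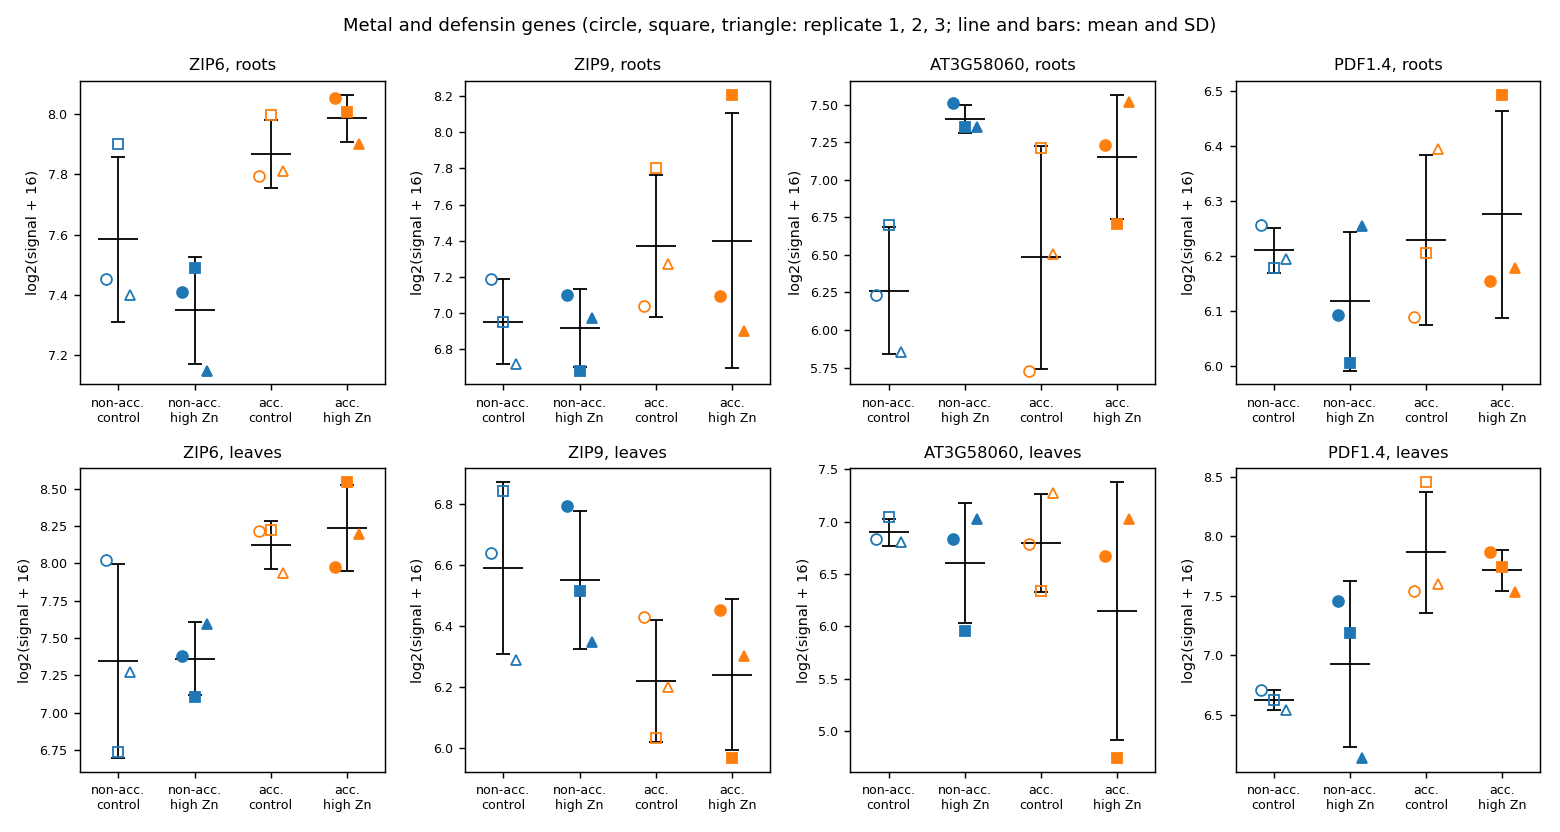
Log2(signal + 16) of ZIP6, ZIP9, AT3G58060 and PDF1.4 in the 12 root arrays (top) and the 12 leaf arrays (bottom), with blue for the non-accumulating and orange for the accumulating bulk, and lines and bars for the group mean and SD. In high-zinc roots ZIP6 lay at 7.90 to 8.05 in the accumulating and 7.15 to 7.49 in the non-accumulating arrays.

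In leaves the sulfate assimilation list of 3 named genes was higher in the accumulating bulk, with a median of 0.39 and an adjusted p of 0.0178. That p was 0.185 with an estimated correlation, 0.0576 with quantile normalization and 0.319 without the leaf arrays of replicate 3. Its member APS4 differed by 0.39 (SE 0.16) and 0 of 3 passed when adjusted over the list alone. The adjusted p of this list also exceeded the threshold, at 0.0503 to 0.0886, without replicate 1 or 3 of the accumulating control, replicate 1 or 3 of the accumulating high-zinc, replicate 3 of the non-accumulating control, or replicate 1 or 3 of the non-accumulating high-zinc leaves. The remaining fixed lists gave adjusted p of 0.133 for photosynthesis markers, 0.636 for the flavonoid and iron deficiency lists, 0.770 for metal export and 0.858 for cold and dehydration. In roots the fixed lists, including those for iron deficiency, metal export, root markers, sulfate assimilation and flavonoids, all gave 0.778.

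For the bulk difference in roots limma called 0 of 12489 probe sets (862 at an unadjusted p under 0.05, 624 expected), and for the bulk difference in leaves 0 of 12685 (546, with 634 expected). By growth medium the counts were 0 in control roots (617 unadjusted), 0 in high-zinc roots (724), 0 for the bulk difference in control leaves (343) and 0 for the bulk difference in high-zinc leaves (404). In leaves array weights gave 234 for both media, 13 in control and 303 in high zinc, and the fit of all 24 arrays gave 4, 1 and 2. In roots 1 probe set was called without replicate 2 of the accumulating control or without replicate 3 of the non-accumulating high-zinc roots, and the latter also gave 1 in high-zinc roots. Leaving out replicate 1 of the non-accumulating control roots gave 0 for both media (769 unadjusted) and 0 in control roots (478 unadjusted). In control leaves 1 was called without replicate 3 of the non-accumulating high-zinc leaves. Across 10755 genes the bulk differences in roots and leaves correlated at r = 0.290.

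Whether the bulks differed in their zinc response was tested by the interaction. In roots the iron deficiency list was lower in this test, with a mean of -0.95 and an adjusted p of 0.00357. BHLH101 stood at -1.18 (SE 0.54) and AT3G12900 at -1.48 (SE 0.96). With an estimated correlation the adjusted p of the list was 0.386, and the exact permutation p of its mean was 0.345. Without replicate 2 of the accumulating control roots the mean was -0.48 (adjusted p = 0.163), and without replicate 2 of the non-accumulating high-zinc roots -0.74 (adjusted p = 0.0669). For single genes limma called 0 for the interaction in roots (470 at an unadjusted p under 0.05, with 624 expected). It called 0 in leaves (197, with 634 expected) and 0 for organ by bulk (372 of 14399, with 720 expected). With array weights the organ by bulk count was 6, and without a filter 1. ZIP6 had an interaction of 0.35 (SE 0.23) in roots and 0.10 (SE 0.43) in leaves, and ZIP9 of 0.07 (SE 0.43) and 0.06 (SE 0.30). Adjusted over the defensin list alone, of which only 2 members were tested in roots, PDF1.2b (1.29, 0.0319) passed for the interaction in roots. PDF1.4 (-0.92, 0.00388) passed over its list for organ by bulk. EXPA7 (1.00) had an unadjusted p of 0.0141 for the interaction in leaves. None of these genes passed over all genes tested. The smallest adjusted p of any probe set was 0.998 for the interaction in roots, 0.9999 in leaves and 0.632 for organ by bulk. The PDF1.2b probe set can cross-hybridise, and its signal averaged over the root groups lay under the filter of the fit of all arrays.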

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

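The tests of a single array and of an exchange of arrays in this part were chosen after the result was seen. In roots, the zinc change of the 5 named iron deficiency genes differed between the bulks by -0.95 on the log2 scale (adjusted p = 0.00357, and 0.386 with an estimated correlation), a difference between groups. An exchange of accumulating control and high-zinc arrays was argued against, since 0 of the 3 high-zinc arrays lay closer to the control arrays of replicates 1 and 3 than to the other high-zinc arrays. A single accumulating control array may account for part of it: replicate 2 had a list mean of 8.90 against 7.39 and 7.56, and without it the difference was -0.48 (adjusted p = 0.163). The call was also lost without replicate 2 of the non-accumulating high-zinc roots (adjusted p = 0.0669), where the difference was -0.74. With all arrays kept, an exact permutation test of the list mean gave p = 0.345 for the difference of -0.95. A difference between the bulks, which the design names, stays open and untested beyond the interaction.

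The rapid stress and immune signalling list, an added list, differed in its zinc change between the bulks in roots by -0.54 (adjusted p = 0.0345, and 0.544 with an estimated correlation), with the p at most 0.220 when replicate 3 of the non-accumulating high-zinc roots was left out. Its bulk difference also differed between roots and leaves, by -0.40 (adjusted p = 0.00228, and 0.790 with an estimated correlation).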

How the results depend on the processing

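The fits without the leaf arrays of replicate 3, the GI covariate, and the omission of single arrays for lists were chosen after the data were seen; the other alternatives were planned. Counts in roots, and the interactions within each organ, were 0 under all planned settings with all arrays kept, except that the fit of all 24 arrays gave 1 for zinc in the non-accumulating roots. For the zinc response in leaves, against 4, the count was 2427 with array weights, 1219 without replicate 3, 111 in the fit of all arrays, 61 with a replicate block, 7 with quantile normalization, 5 with the GI covariate, and 2 without a trend or without a filter. For the zinc response of the non-accumulating bulk in leaves, against 1, it was 759, 408 and 2 with array weights, without replicate 3 and in the fit of all arrays, and 0 without a filter. For the zinc response of the accumulating bulk in leaves, against 0, it was 1193, 217 and 7 under these settings, and 7 with a replicate block. For the bulk difference in leaves, against 0, it was 234 with array weights, 4 in the fit of all arrays, and 1 without replicate 3, without a filter or with a replicate block. For the bulk difference in control leaves it was 13, 1 and 2 with array weights, in the fit of all arrays and without replicate 3, and for the bulk difference in high-zinc leaves 303 with array weights, 2 in the fit of all arrays and 1 without a filter. The organ by bulk count was 6 with array weights and 1 without a filter, and the root against leaf count was 6407 with the 75th percentile filter, which tested 8274 probe sets. Except for that smaller number tested, the cause was not tested.

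Of the fixed lists in the averaged comparisons, interactions and root against leaf, 6 tests passed at the preset correlation, 0 with an estimated correlation and 11 without a filter. The adjusted p with an estimated correlation was 0.0618 for iron deficiency genes and zinc in roots, 0.386 for their interaction, 0.447 for the wider photosynthesis list and zinc in leaves, and 0.185 for sulfate assimilation and bulk in leaves, which gave 0.0576 with quantile normalization and 0.319 without replicate 3. The bulk difference of the photosynthesis list's mean in leaves, -0.19, shrank to -0.04 without replicate 3 of the non-accumulating high-zinc leaves. Only its direction relative to other genes turned there (adjusted p = 0.941). It was -0.35 without replicate 3 of the accumulating high-zinc leaves (adjusted p = 1.875e-05).

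With single arrays left out, where a group of 2 arrays shares the pooled spread, counts ranged from 1 to 12 for zinc in leaves, 0 to 1 in non-accumulating leaves, 0 to 6 for zinc in roots, 0 to 10 in non-accumulating roots, 0 to 1 for bulk in roots, in high-zinc roots and in control leaves, and 9524 to 9911 for root against leaf. From 3 to 7 of these fixed-list tests passed, and the adjusted p ranged from 1.69e-09 to 7.67e-06 for iron deficiency genes and zinc, 0.000225 to 0.163 for their interaction, 5.32e-15 to 1.80e-06 for the photosynthesis list and zinc in leaves, and 0.00132 to 0.0886 for sulfate assimilation.

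Replicate numbers were checked for pairing across groups. The correlation of deviations from group means exceeded 0.1 in 11 of 18 pairs of root arrays and 15 of 18 pairs of leaf arrays with the same number, and in 4 of 48 pairs of root with leaf arrays. Because some pairs stayed under 0.1, the numbers were not used as pairs in any test outside the replicate block. Even so, 8 of 12 root arrays and 9 of 12 leaf arrays correlated best with their own number. The labels do not say how replicates were made, so a batch shared by arrays of the same number stays possible. Same-number pairs had a mean correlation of 0.304 in leaves and 0.147 in roots, against -0.142 and -0.073 for other pairs. In leaves the main fits therefore left a shared replicate effect in the spread, and the replicate block called more probe sets for zinc there. Genes with signals near the filter lie close to background, where small changes are not resolved.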

Other observations

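The tests of added lists, of leaves without replicate 3, of the GI covariate, of the actin ratio, of list means without single arrays and of plastid-encoded genes were chosen after the probe table or the result was seen. In high-zinc leaves the ER body list, which holds NAI2 and jacalin-related genes, was higher when averaged over both bulks. Its median was 0.48 over 6 members with an adjusted p of 0.00116, and that p was 0.151 with an estimated correlation. The list mean differed by 0.31 in the non-accumulating and 0.49 in the accumulating bulk, each with an exact p of 0.1. The latter was 0.32 without replicate 3 of the accumulating high-zinc leaves. JAL34 (0.44) and JAL23 (0.53) passed when adjusted over the list alone. The exact permutation p of the list mean was 0.005, the smallest the design can give. Lists for this test were picked after they had passed camera in the same arrays, so it is not separate support. The wider glucosinolate list was higher with a median of 0.49 over 5 members (adjusted p = 0.0103, and 0.244 with an estimated correlation; exact permutation p = 0.005), with the transporter gene GTR1 at 0.89 and UGT74B1 at 0.46 past the threshold over the list alone. Without the leaf arrays of replicate 3 the medians of these lists were 0.21 and 0.40, still positive, with adjusted p of 0.306 and 0.333. Without replicate 3 of the accumulating or non-accumulating control leaves the wider glucosinolate list gave 0.0594 and 0.0556 (list glucosinolate, wider list, zinc response in leaves).

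In leaves of the accumulating bulk the same ER body list was higher than in the non-accumulating bulk (median 0.30, adjusted p = 0.00142, and 0.162 with an estimated correlation), with JAL33 at 0.99 and JAL22 at 0.55 past the threshold over the list alone. The rapid stress list was also higher (median 0.26, adjusted p = 0.00142, and 0.827 with an estimated correlation), the sign was positive in all 13 members, and the mean difference of 0.33 was 0.15 without replicate 3 of the non-accumulating high-zinc leaves (adjusted p = 0.116) and 0.56 without replicate 3 of the accumulating high-zinc leaves. It was 0.21 without replicate 3 of the non-accumulating control, and 0.22 without replicate 1 of the accumulating control or replicate 2 of the accumulating high-zinc leaves, the last with an adjusted p of 0.0568 (list rapid stress and immune signalling, bulk difference in leaves). The wider photosynthesis list was lower with a median of -0.18 (adjusted p = 0.0345, and 0.910 with an estimated correlation), and without replicate 3 of the non-accumulating high-zinc leaves the difference of the list mean shrank from -0.19 to -0.04 (adjusted p = 0.941). Across single arrays left out, this difference ranged from -0.35, without replicate 3 of the accumulating high-zinc leaves, to that value. In high-zinc leaves the rapid stress list was higher with a median of 0.33 (adjusted p = 0.0268, and 0.610 with an estimated correlation), with a list mean difference of 0.34 (exact permutation p = 0.325). The same list was lower in leaf replicate 3 than in replicates 1 and 2 by a median of -0.73 (adjusted p = 2.48e-06, and 0.0715 with an estimated correlation). Without single arrays the difference ranged from 0.18, without replicate 3 of the accumulating control, to 0.56, without replicate 3 of the accumulating high-zinc leaves. It was 0.53 without replicate 3 of the non-accumulating high-zinc leaves, and 0.22 without replicate 3 of the non-accumulating control or replicate 2 of either high-zinc group. For the list rapid stress and immune signalling, zinc response in leaves, the adjusted p was 0.270 and 0.128 without replicate 3 of the accumulating or non-accumulating control. It was 0.0664 and 0.207 without replicate 1 or 2 of the accumulating high-zinc leaves, and 0.0849 and 0.189 without replicate 1 or 2 of the non-accumulating high-zinc leaves.

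Mitochondria-encoded genes were higher in high-zinc leaves with a median of 0.35 over 13 members (adjusted p = 0.0108, and 0.610 with an estimated correlation), and the p was at most 0.238, without replicate 3 of the accumulating control leaves. In leaf replicate 3 these genes were lower than in replicates 1 and 2 by a median of -0.76 (adjusted p = 8.43e-07, and 0.164 with an estimated correlation).

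The higher signals of iron deficiency genes in high-zinc roots were weighed against differences in RNA and tissue. RNA integrity stays open: the GAPDH ratio differed by -0.00730 between zinc levels, so adding it could move nothing (change of the list mean 1.18, 95% interval 0.42 to 1.93, and 1.17 without it), and the actin ratio was higher with zinc by 0.18 (-0.02 to 0.39) and left a change of 1.00 (0.09 to 1.92). Another share of root tissues stays open as well: with the root marker mean as a covariate the change was 0.94 (95% interval -0.08 to 1.95), which keeps most of its size with a wider interval. A response of these named genes to zinc, the factor the design varied, may be the source and was not tested apart from it.

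The lower signals of photosynthesis genes in high-zinc leaves, -0.50 (95% interval -1.02 to 0.02), could not be told apart from time of day at harvest or less green tissue. With GI as a covariate for time of day the change was -0.38 (-0.94 to 0.18), and relative to plastid-encoded genes, a test of less green tissue, -0.40 (-1.07 to 0.26). Each interval includes 0, as does the interval before any covariate, because replicate 3 of both high-zinc groups lay near the controls. RNA integrity was not tested by its ratios, which differed by -0.00225 (GAPDH) and 0.03 (actin) between zinc levels, so that adding them moved nothing (-0.49, -1.03 to 0.04, and -0.49, -1.06 to 0.09). A response to zinc stays open as well.

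Other splits of the same arrays were counted to see whether counts as large arise by chance, with 100 splits for comparisons of more than 3 against 3. For root against leaf 1 of 100 splits, the real one, gave a count as large as 9776, and the highest other count was 0. That is the smallest share these splits can give. Splits that mix the organs put the organ difference into the spread, so low counts there were likely beforehand. For zinc in leaves 2 of 100 gave at least 4, and the highest other count was 1153. That split exchanged control replicate 3 with high-zinc replicate 2 in both bulks, which puts the arrays of replicate 3 on the same side and points to their structure. Where the real count was 0, any split reaches it (100 of 100), so the splits test nothing there. Their highest other counts were 19, 3 and 2 for the bulk difference, zinc and the interaction in roots. For bulk in leaves, the leaf interaction and organ by bulk they were 1383, 434 and 895, which point to a structure of the arrays. With 10 splits for 3 arrays against 3, or 18 for leaves without replicate 3, a share under 0.05 cannot be reached. The real and highest other counts were 1 and 0 for zinc in non-accumulating leaves (1 of 10), 0 and 1 for zinc in non-accumulating roots and for bulk in high-zinc leaves, 0 and 0 for the remaining comparisons (10 of 10), and 1219 and 0 for leaves without replicate 3 (1 of 18).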
